A study of Rattus with 6 samples.

How the data were processed

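RNA was sequenced from 6 samples of rat bone marrow mesenchymal stem cells (BMSC), 3 labelled control and 3 labelled as treated with dexamethasone, a synthetic glucocorticoid, at 100 uM for 4 days. The dose is printed as the labels give it and could not be checked from the counts, and whether the controls received vehicle is not given in the sources used here. Samples were grouped by the titles and descriptions in the labels, because the treatment tag in the labels reads DEX for all 6 samples. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a SMARTER mRNA-seq kit. The labels do not say whether the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

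The deposited values were read counts per gene for all 6 libraries in a single table, with the chromosome, start, end, strand and length of each gene's exons, per the file headers. The authors' aligner, counting program, strand setting and treatment of reads that map to several genes are not given in the sources used here. Per the submitters' processing notes the genome build was mm10, a mouse build. The table itself held rat symbols: 17432 of its 30211 gene names were in a rat gene table (assembly GRCr8), and 17302 of the 17408 with a numbered or lettered chromosome in both lay on the same chromosome. It also held 877 genes on chromosome 20, which the mouse genome lacks, and 7671 genes named after rat contigs. Coordinates are therefore printed as the table gives them, in a rat build that is not given in the sources used here, and none was taken from the rat gene table. Exons of 78 genes were listed on several chromosomes or scaffolds. No column belonged to another sample, and every line of the table named a gene.

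Library totals ranged from 34835072 to 41676315 counts. Of the 26067 values between 1 and 20 counts, 70.3% were even (69.0% to 71.5% by library), against 50.6% of values of 1000 or more. Because low values came so often in steps of 2, a floor was set at 6 counts, taken as 3 read pairs, and counting intervals were computed on counts divided by 2 and rounded up. That floor was chosen after the low values were seen. It came to 0.142 to 0.170 CPM (counts scaled to a common library size) by library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

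Genes were filtered with filterByExpr by group, which kept 14111 and left out 16100, of which 9819 had no count in any library. Counts were scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3): dispersions and the quasi-likelihood fit were estimated robustly, dexamethasone was tested against control with no covariate, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p below 0.05. Fold changes are dexamethasone over control. Levels are TMM-scaled CPM as mean ± SD. Standard errors of log2 fold changes were taken from the spread of log2 CPM (prior count 2) between the replicates. A fold against a group with no count is a lower bound, computed from the floor over the whole group. With 1 to 3 read pairs in a group, the ratio of counts is given with an exact 95% binomial interval.

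For the description by pathway and cell type, 27 gene lists were written from general knowledge of marrow stroma and glucocorticoids. They covered glucocorticoid receptor targets, osteoblast, adipocyte and chondrocyte genes, cell cycle phases, inflammation, interferon, complement, matrix, Wnt signalling, contractile genes, stress responses, metabolism and markers of stromal, macrophage, osteoclast, endothelial, granulocyte, lymphocyte and erythroid cells. The 22 lists with at least 5 tested members were compared with the other genes by camera in limma 3.58.1, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes. Members past the threshold were counted by the adjustment over all genes and adjusted over the list alone.

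The genes named were of 3 kinds: 15 fixed genes, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM, non-overlapping groups and a conventional symbol, and for each list the 3 members with the smallest p, or all called members where there were 1 or 2. Together these made 95 genes, of which some are not reported here. Other genes are named only where stated as chosen after their values were seen. The grouping, the test, the lists, this rule and the settings listed first below were set before the data were examined.

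The scripts were tested on simulated data for this comparison, with 14111 genes drawn from the libraries' own means and sizes. Of the simulated changed genes, 26 of 48 were recovered at 1.2-fold, 42 of 49 at 1.5-fold, 47 of 50 at 2-fold and 48 of 48 at 4-fold, with 13 false calls, and 0 of 20 lists of unchanged genes were called. Far fewer genes were changed there than were called in the data, so these shares do not measure the recovery in the data. Genes were drawn independently, so the unchanged lists do not check the preset correlation between genes. Pairs of replicates were compared by chi-square over genes, which gave 2.70 to 4.16 per degree of freedom. All lay above the value of 2 that steps of 2 counts alone would give, so no pair was treated as a library deposited more than once. This does not tell separate cultures from repeat libraries of the same RNA.

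The results were recomputed with DESeq2 size factors, library size alone and upper quartile scaling, no filter on low counts, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, each replicate left out in turn, the replicate number as a block, and library sizes and TMM factors without the 20 most counted genes, which stayed in the test. After the data were seen, tests with a biological coefficient of variation of 0.2, against a fold change of 1.5 and on halved counts were added. The first of these used a likelihood ratio test in place of the quasi-likelihood test. Without known strand, reads of a gene and of one overlapping it cannot be told apart. This concerned 5 of the named genes: Aox3, Fbn1, Tagln, Sqstm1 and Mt-co3. Reads shared between close relatives, such as Cxcl1, Cxcl2 and Cxcl3 or Mt1 and Mt2A, may have been split between them, so values of single members are uncertain.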

Results

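Gene expression was measured by RNA sequencing in rat bone marrow mesenchymal stem cells, the stromal cells that can form bone, fat and cartilage, after 4 days with or without 100 uM dexamethasone. There were 3 control and 3 dexamethasone libraries. Control replicates 1 to 3 held 39156705, 40201930 and 40291671 counts, and dexamethasone replicates 1 to 3 held 41676315, 34835072 and 40044978. Between 17087 and 17356 genes had a count in each library. Counts of mitochondrially encoded genes made up 2.02% to 2.15% of each library, and the 20 most counted genes 7.76% to 8.56%. The comparison asked which genes differed between the dexamethasone and control libraries.

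Established targets of the glucocorticoid receptor were examined per library, since the labels' treatment tag did not separate the groups. Fkbp5, a co-chaperone of that receptor (chromosome 20, 7976713 to 8019020), had 69.1, 71.0 and 69.3 CPM (TMM-scaled) in the controls and 1290, 1390 and 1430 CPM with dexamethasone. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein (chromosome X, 111884295 to 111887906), had 15.4, 18.1 and 17.6 CPM against 129, 124 and 123 CPM. Per1, a clock gene (chromosome 10, 55687050 to 55695994), had 14.6, 14.5 and 15.5 CPM against 48.3, 46.5 and 43.0 CPM. The 3 genes were higher in 3 of 3 libraries labelled dexamethasone, with adjusted p of 1.7e-44, 1.9e-39 and 3.6e-27 and log2 fold changes of 4.30 ± 0.046, 2.88 ± 0.076 and 1.63 ± 0.059 (SE) (edgeR's quasi-likelihood test, Benjamini-Hochberg).

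Of 14111 tested genes, 9027 (64.0%) differed between the dexamethasone and control libraries, of which 4559 rose and 4468 fell. The threshold was an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say whether replicates were separate cultures. If each group came from a single culture, these calls could not tell dexamethasone from a difference between cultures. Most changes were small: 6819 of the calls (75.5%) were under 2-fold, and the median size of a called change was 0.48 on the log2 scale. At least 2-fold changes numbered 2208, with 1220 up and 988 down, and 414 genes rose and 418 fell at least 4-fold. The values of the 2 groups did not overlap for 9445 genes (66.9%), where chance gives 10%. Replicates differed little, with a common biological coefficient of variation of 3.66%, correlations of log2 CPM of at least 0.994 within groups against 0.936 to 0.937 between them, and 88.6% of the variance on the first principal component. With the coefficient of variation set to 0.2, a setting chosen after seeing the data, 3693 genes passed, 1993 up and 1700 down. Tested against a fold change of 1.5, also chosen afterwards, 2827 passed, 1549 up and 1278 down.

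**Figure D1:**
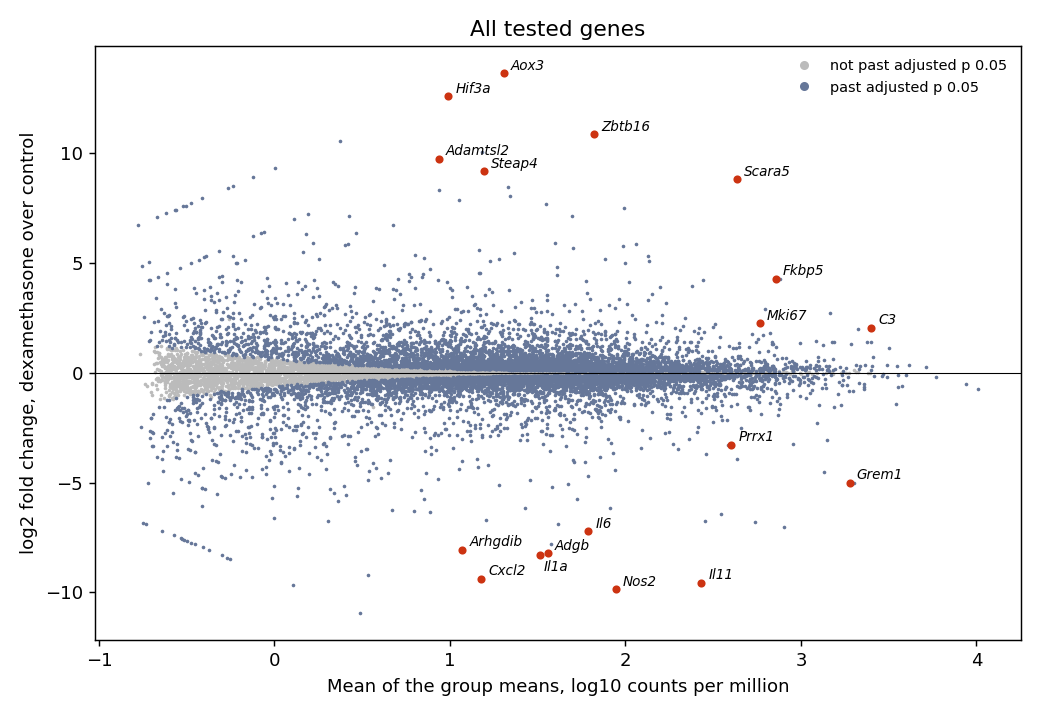
Each point is a tested gene, with the mean of the 2 group means on the horizontal axis (log10 CPM) and the log2 fold change of dexamethasone over control on the vertical axis. Called genes are blue, others grey and named genes red. The red points include the 6 largest rises, led by Aox3 and Hif3a, and the 6 largest falls, led by Nos2 and Il11. Both rankings cover only called genes with a mean of at least 5 CPM, non-overlapping groups and a conventional symbol.

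Rises and falls were ranked among called genes with a mean of at least 5 CPM, non-overlapping groups and a conventional symbol. Within these limits, the 6 largest rises were in genes almost silent in the controls. Aox3, an aldehyde oxidase (chromosome 9, 65013862 to 65099433), had no count in 3 controls and 40.5 ± 1.30 CPM (SD, n = 3) with dexamethasone, at least 797-fold higher by the floor over the group. Its exons overlap AABR07067810.2, so some of its reads may belong to that gene. Hif3a, a hypoxia-inducible factor subunit (chromosome 1, 78976318 to 78997869), went from no count to 19.6 ± 1.03 CPM, at least 384-fold higher. Zbtb16, a zinc finger transcription factor (chromosome 8, 52985313 to 53146953), rose from 0.068 ± 0.031 to 133 ± 1.37 CPM, a log2 fold change of 10.87 ± 0.20 (SE). Its controls held only 8 counts in all, so this SE, taken with a prior count of 2, understates the counting error. Adamtsl2, a secreted matrix protein (chromosome 3, 5624506 to 5654910), had 2 counts in the controls and 2036 with dexamethasone, a ratio of 1020 (95% interval 182 to 40200). Steap4, a metalloreductase (chromosome 4, 23090029 to 23135354), had 6 and 3691 counts, a ratio of 615 (210 to 2990). Scara5, a scavenger receptor for ferritin (chromosome 15, 49069145 to 49177166), rose from 1.92 ± 0.056 to 860 ± 4.37 CPM, a log2 fold change of 8.81 ± 0.024.

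Among the largest falls, 4 were inflammatory mediators. Nos2, the inducible nitric oxide synthase (chromosome 10, 66189786 to 66313190), fell from 176 ± 2.69 to 0.179 ± 0.146 CPM, a log2 fold change of -9.86 ± 0.66 (SE). Il11, a cytokine (chromosome 1, 72635267 to 72643255), fell from 540 ± 14.1 to 0.703 ± 0.307 CPM. Cxcl2, a chemokine (chromosome 14, 18731378 to 18733391), had 3552 counts in the controls and 5 with dexamethasone, a ratio of control to dexamethasone of 592 (95% interval 202 to 2870). Il1a, which encodes interleukin-1 alpha (chromosome 3, 121825412 to 121836086), fell from 65.0 ± 0.196 to 0.210 ± 0.122 CPM. Adgb, which encodes androglobin (chromosome 1, 4445027 to 4560789), fell from 71.9 ± 1.32 to 0.240 ± 0.038 CPM. Arhgdib (chromosome 4, 170913923 to 170932618), fell from 23.4 ± 1.34 to 0.086 ± 0.035 CPM. The adjusted p of these 12 genes was at most 4.4e-32 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

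**Figure D2:**
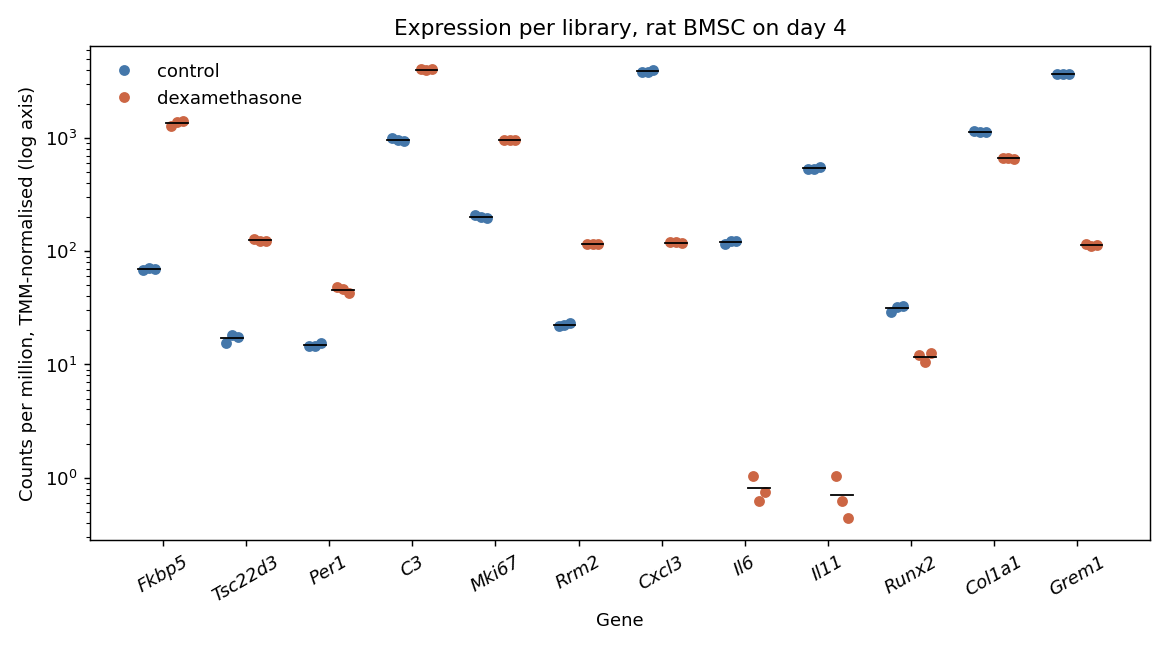
CPM of 12 named genes in each library, on a log axis, with controls in blue, dexamethasone in orange and a bar at each group mean. The groups are separate for every gene drawn, from Fkbp5 at 69.8 and 1370 CPM to Il6 at 122 and 0.802 CPM.

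Of 25 tested glucocorticoid receptor targets, 21 rose, 3 fell and 1 did not pass, with a median log2 fold change of 1.76. Gpx3, a secreted glutathione peroxidase, rose from 3.48 ± 0.331 to 189 ± 6.82 CPM (SD, n = 3), and Mt2A, a metallothionein, from 24.6 ± 1.12 to 243 ± 4.58 CPM. The members that fell, named after their values were seen, were Nfkbia (log2 -0.14), Angptl4 (-0.81) and Bcl6 (-0.15), and Ddit4 did not pass (-0.01). Nfkbia and Bcl6 were not called with the coefficient of variation set to 0.2 (adjusted p = 0.769 and 0.734) or against a fold of 1.5 (adjusted p = 1 for both). The call of Bcl6 was also lost with library size alone (adjusted p = 0.092) and without control replicate 1 (0.118) or 2 (0.0576) or dexamethasone replicate 1 (0.0531) or 3 (0.156). Adjusted over the list alone, the counts of members were the same for this and all other fixed lists except the contractile and cholesterol lists. The median was 1.76 also with Hif3a at its bound. The list stood above other genes (camera, adjusted p = 8.7e-44, and 0.00154 with an estimated correlation). Nr3c1, the receptor itself, fell from 202 ± 2.80 to 149 ± 2.81 CPM, a log2 fold change of -0.44 ± 0.019 (SE). That call did not hold with the coefficient of variation set to 0.2 (adjusted p = 0.174) or against a fold of 1.5 (adjusted p = 1). Hsd11b1, which regenerates active glucocorticoid inside cells, fell from 465 ± 17.6 to 158 ± 3.61 CPM.

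Inflammatory genes had the lowest median of the 22 lists compared. Of 25 tested cytokines, chemokines and proteases, 24 fell and 1 rose, with a median log2 fold change of -5.03 (camera, adjusted p = 5.1e-122, and 0.00154 with an estimated correlation). Cxcl3, a neutrophil chemokine, fell from 3899 ± 71.0 to 120 ± 0.881 CPM (SD, n = 3), Cxcl6 from 1089 ± 18.7 to 9.82 ± 0.659 CPM, and Ccl2, a monocyte chemokine, from 563 ± 6.87 to 5.26 ± 0.646 CPM. Il6 fell from 122 ± 3.90 to 0.802 ± 0.216 CPM, 149-fold lower. The member that rose, named after its value was seen, was Csf1 (log2 0.18), a macrophage growth factor, which did not pass with the coefficient of variation set to 0.2 (adjusted p = 0.675) or against a fold of 1.5 (adjusted p = 1). Macrophage markers moved with this group at low levels: of 8 tested out of 22, 0 rose, 4 fell and 4 did not pass, with a median control level of 1.0 CPM and a median log2 fold change of -1.23. Cd74, Cd53 and Cd68 fell from 1.74, 1.40 and 1.21 CPM to 0.139, 0.127 and 0.509 CPM. The macrophage list was not called against other genes (camera, adjusted p = 0.455).

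Complement and acute-phase genes went the other way. Of 14 tested, 12 rose, 1 fell (C2, log2 -0.87) and 1 did not pass (C4a, log2 0.61), both named after their values were seen, and the median log2 fold change was 1.73 (camera, adjusted p = 1.7e-21, and 0.0207 with an estimated correlation). C3, the central complement component, rose from 969 ± 24.7 to 4042 ± 71.3 CPM (SD, n = 3). Orm1, an acute-phase protein, rose from 0.695 ± 0.120 to 98.2 ± 0.857 CPM, and Serping1, the inhibitor of complement C1, from 64.7 ± 3.05 to 370 ± 1.89 CPM. Of 23 tested interferon response genes, 15 rose, 5 fell and 3 did not pass, and the list was not called against other genes (camera, adjusted p = 0.385). Bst2 rose by 1.26 on the log2 scale, while Rsad2 fell by 2.36.

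Cell cycle genes rose together. All 27 tested G2/M genes rose, with a median log2 fold change of 1.45 (camera, adjusted p = 2.0e-29, and 0.00154 with an estimated correlation). All 27 tested genes of S phase and DNA replication rose, with a median of 1.23 (adjusted p = 1.4e-19, and 0.00321 with an estimated correlation). Mki67, a marker of cycling cells, rose from 202 ± 7.42 to 963 ± 2.55 CPM (SD, n = 3). Cenpe, a kinetochore motor, and Birc5, which encodes survivin, rose by 1.61 and 2.44 on the log2 scale. Rrm2, a subunit of ribonucleotide reductase, rose by 2.37, and Mcm3 and Mcm6, subunits of the replicative helicase, by 1.79 and 1.71. Ccnd1, which encodes cyclin D1 and was among the Wnt targets, rose by 0.25, a call that did not hold with the coefficient of variation set to 0.2 (adjusted p = 0.531) or against a fold of 1.5 (adjusted p = 1).

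**Figure D3:**
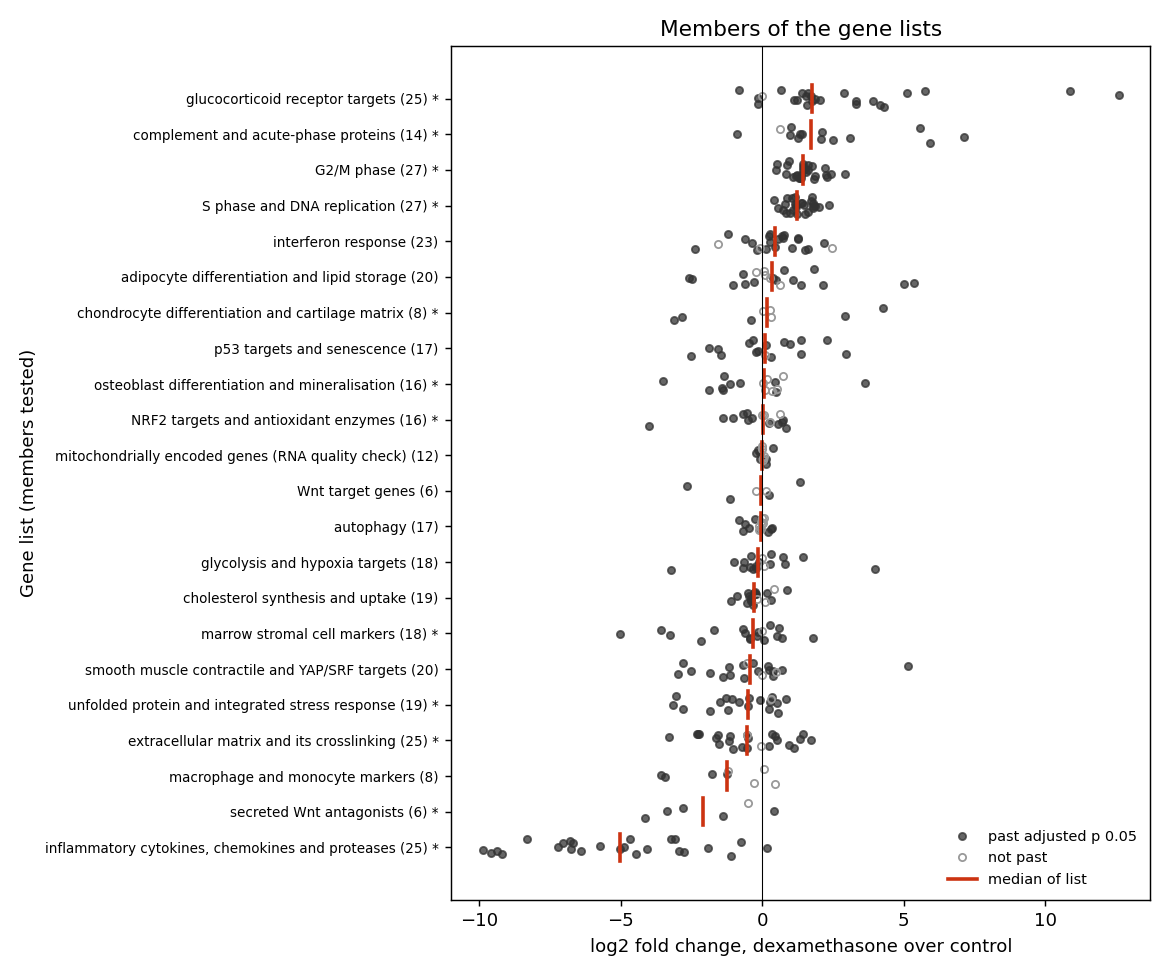
Log2 fold change of dexamethasone over control for each tested member of the 22 lists compared with other genes, with filled points past an adjusted p of 0.05, open points not past it, and a red bar at each median. Lists called by camera carry an asterisk, and medians run from -5.03 for the inflammatory list to 1.76 for glucocorticoid receptor targets.

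Genes of bone formation moved both ways. Of 16 tested osteoblast genes, 3 rose, 7 fell and 6 did not pass. The median log2 fold change was 0.06 while the mean was -0.31 and the test pointed down (camera, adjusted p = 0.0315). The list was not called with an estimated correlation (adjusted p = 0.121) or with limma-voom (adjusted p = 0.206). Runx2, the transcription factor that commits cells to bone, fell from 31.3 ± 1.93 to 11.7 ± 1.15 CPM (SD, n = 3). Cdh11, osteoblast cadherin, fell from 273 ± 7.53 to 73.9 ± 1.22 CPM, Bmp2, a bone morphogenetic protein, from 15.3 ± 0.460 to 1.35 ± 0.042 CPM, and Col1a1, a chain of type I collagen, from 1138 ± 16.4 to 665 ± 8.43 CPM. The 3 that rose, named after their values were seen, were Omd, a proteoglycan of mineralised matrix, Sparc (log2 0.50) and Spp1 (0.45). Omd had 6 counts in the controls and 78 with dexamethasone, a ratio of 13 (95% interval 4.13 to 65.7). Sparc and Spp1 did not pass with the coefficient of variation set to 0.2 (adjusted p = 0.113 and 0.165) or against a fold of 1.5 (adjusted p = 1 for both). Alpl, the alkaline phosphatase of mineralising cells, was near the floor in both groups, at 0.307 ± 0.141 and 0.348 ± 0.019 CPM (36 and 41 counts), and did not pass (adjusted p = 0.740, edgeR's quasi-likelihood test with Benjamini-Hochberg). Tnfrsf11b, which encodes the osteoclast inhibitor osteoprotegerin, rose from 43.8 ± 1.72 to 103 ± 0.967 CPM. Its ligand gene Tnfsf11 and the bone inhibitor Sost had 0 counts in all 6 libraries, which allows up to 0.170 CPM in the least deep.

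Fat and cartilage genes also moved both ways. Of 20 tested adipocyte genes, 9 rose, 6 fell and 5 did not pass, and the list was not called against other genes (camera, adjusted p = 0.363). Pparg, the master regulator of fat cells, stood at 1.22 ± 0.305 and 1.32 ± 0.116 CPM (SD, n = 3) and did not pass (adjusted p = 0.722, edgeR's quasi-likelihood test with Benjamini-Hochberg). Fabp4, a fatty acid binding protein of mature fat cells, had 0 counts in the controls and 8 with dexamethasone and was not tested. Ebf1, a transcription factor, and Plin4, a lipid droplet protein, rose by 1.81 and 5.37 on the log2 scale, and Plin2, another such protein, fell by 0.68. Of 8 tested chondrocyte genes, 2 rose, 3 fell and 3 did not pass. That list was called upward (camera, adjusted p = 5.5e-04), but not with an estimated correlation (adjusted p = 0.0518), without the filter on low counts (adjusted p = 0.221) or with limma-voom (adjusted p = 0.592). The members that rose were Prg4, the joint lubricant lubricin, from 74.6 ± 1.37 to 1436 ± 71.9 CPM, and Col11a1, a fibrillar collagen, from 146 ± 2.40 to 1105 ± 7.37 CPM. Sox9, the main transcription factor of cartilage, fell from 23.7 ± 0.946 to 2.75 ± 0.153 CPM.

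Matrix and stromal genes fell more often than they rose. Of 25 tested matrix genes, 9 rose, 14 fell and 2 did not pass, with a median log2 fold change of -0.53 (camera, adjusted p = 1.1e-05, but adjusted p = 0.0658 with an estimated correlation). Fbn1, which encodes fibrillin-1, fell from 2048 ± 33.9 to 416 ± 4.50 CPM (SD, n = 3), Tnc, which encodes tenascin-C, from 697 ± 10.5 to 71.5 ± 4.09 CPM, and Col12a1 from 518 ± 4.59 to 110 ± 3.86 CPM. Fbn1 overlaps AABR07053635.1. Of 18 tested markers of marrow stroma, 6 rose, 11 fell and 1 did not pass, with a median of -0.31 (camera, adjusted p = 1.6e-09, and 0.0207 with an estimated correlation). Grem1, a secreted antagonist of bone morphogenetic proteins, fell from 3669 ± 13.1 to 113 ± 1.70 CPM, Prrx1, a mesenchymal transcription factor, from 727 ± 19.2 to 75.6 ± 2.51 CPM, and Cd200, a surface glycoprotein, from 68.7 ± 0.721 to 5.76 ± 0.189 CPM. Of 20 tested contractile genes, 6 rose and 11 fell, or 12 fell adjusted over the list alone, and the list was not called (camera, adjusted p = 0.191), except without the filter on low counts (adjusted p = 0.0438). Tpm1 and Tagln fell (log2 -1.13 and -2.81), while Lmod1, leiomodin of smooth muscle, rose by 5.16 on the log2 scale. Tagln overlaps Sidt2.

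Genes listed as Wnt antagonists were lower, with 1 rise, 4 falls and 1 not passing among 6 tested. Their median log2 fold change was -2.09 (camera, adjusted p = 0.00193, but adjusted p = 0.0658 with an estimated correlation). The member that rose, named after its value was seen, was Kremen1, which encodes a membrane receptor and not a secreted protein. That call did not hold with the coefficient of variation set to 0.2 (adjusted p = 0.235) or against a fold of 1.5. Sfrp4, Dkk3 and Sfrp2 fell (log2 -3.35, -4.12 and -2.79), from 83.1, 6.86 and 6.78 CPM in the controls. Among 6 tested Wnt targets, 2 rose, 2 fell and 2 did not pass, and the list was not called against other genes (camera, adjusted p = 0.329). Ccn4 and Tcf7 were the members that fell (log2 -2.67 and -1.15). Ccnd1 and Rnf43, the latter named after its value was seen, were those that rose (log2 0.25 and 1.34), and the call of Rnf43 was lost without control replicate 2 (adjusted p = 0.076), without dexamethasone replicate 2 (0.0635) and against a fold of 1.5 (0.0815).

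Stress response genes fell as a group where they belonged to the unfolded protein and integrated stress responses. Of 19 tested, 6 rose, 12 fell and 1 did not pass, with a median log2 fold change of -0.49 (camera, adjusted p = 6.7e-06, and 0.0404 with an estimated correlation). Chac1, Trib3 and Atf3, which are induced when the integrated stress response is active, fell (log2 -3.15, -3.04 and -2.80). Against a fold of 1.5, 1 rise and 9 falls passed. The calls of Calr, Hsp90b1, Pdia4, Dnajb9, Sdf2l1, Creld2, Manf and Psat1, named after their values were seen, were lost there. Xbp1 was the member that did not pass (adjusted p = 0.352). The 2 responses were not tested apart, so a fall of the unfolded protein response alone is not shown. Of 16 tested NRF2 targets and antioxidant genes, 5 rose, 7 fell and 4 did not pass. The median was 0.02, the mean -0.28 and the test pointed down (camera, adjusted p = 0.0448, but adjusted p = 0.36 with an estimated correlation). That call was also lost with library size alone (adjusted p = 0.0598), limma-voom (0.365), halved counts (0.0504), and without dexamethasone replicate 2 (0.0516) or 3 (0.0586). Slc7a11, the cystine transporter, fell by 3.98 on the log2 scale. Sod3, the extracellular superoxide dismutase, fell by 1.40. Of 17 tested p53 targets, 8 rose, 8 fell and 1 did not pass, with a median of 0.11 and a mean of 0.10 while the test pointed down without passing (camera, adjusted p = 0.482). Sesn1 rose by 2.96 on the log2 scale, and Pmaip1 and Sesn2 fell (log2 -2.53 and -1.88).

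Metabolic lists were not called against other genes. Of 18 tested glycolysis and hypoxia genes, 6 rose, 10 fell and 2 did not pass, with a median log2 fold change of -0.16, a mean of 0.02 and a test that pointed up (camera, adjusted p = 0.82). Vegfa, the vascular growth factor, fell from 1628 ± 6.09 to 174 ± 4.95 CPM (SD, n = 3). Pfkfb3, a regulator of glycolysis, rose from 28.6 ± 1.33 to 449 ± 14.7 CPM, and Bnip3, a mitophagy receptor, from 93.2 ± 0.887 to 255 ± 5.60 CPM. Of 19 tested cholesterol genes, 3 rose and 13 fell, or 14 fell adjusted over the list alone (camera, adjusted p = 0.147). Without the filter on low counts and with limma-voom that list was called (adjusted p = 0.0438 and 0.0216). Msmo1, Insig1 and Fdft1 fell (log2 -1.11, -0.89 and -0.55). Of 17 tested autophagy genes, 3 rose, 6 fell and 8 did not pass (camera, adjusted p = 0.482). Sqstm1, which overlaps Mrnip, and Gabarapl2 fell (log2 -0.69 and -0.60), and Map1lc3b rose (0.33). Among 12 mitochondrially encoded genes, 3 rose, 4 fell and 5 did not pass (camera, adjusted p = 0.989). That balance turned with library size alone (4 rose and 2 fell) and without control replicate 1 or dexamethasone replicate 1 (5 and 3 in each case). Mt-co3, which overlaps Mt-atp6, and Mt-cyb fell (log2 -0.20 and -0.13), and Mt-nd3 rose (0.39). The calls of Fdft1, Map1lc3b and these 3 mitochondrial genes did not hold with the coefficient of variation set to 0.2 (adjusted p of 0.0721, 0.359, 0.625, 0.776 and 0.259 in the order named). None of these 5 genes, nor Gabarapl2, passed against a fold of 1.5.

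Markers of other marrow cells were scarce. Of 10 osteoclast markers 3 were tested, and Nfatc1, which also acts outside osteoclasts, fell by 2.99 on the log2 scale. Of 12 endothelial markers 11 had a symbol in the data and 4 were tested. Flt1, Vwf and Egfl7 fell (log2 -1.34, -2.15 and -0.60), and Tek rose (0.81), the last named after its value was seen. The call of Egfl7 did not hold with the coefficient of variation set to 0.2 (adjusted p = 0.0672) or against a fold of 1.5 (adjusted p = 0.794), and the call of Tek was lost against that fold (adjusted p = 0.312) and without control replicate 3 (0.0852) or dexamethasone replicate 1 (0.0512). Of 12 granulocyte markers 1 was tested (Ngp) and did not pass. Of 12 lymphocyte markers 0 were tested. Of 12 erythroid markers only 9 had a symbol in the data, and 2 were tested, so the absent ones could not be measured. S100a8, a granulocyte marker left out by the filter on low counts, had 0 counts in the controls and 41 with dexamethasone, and it was called in the settings that tested it, which were no filter (adjusted p = 1.02e-06) and leaving out any control replicate or dexamethasone replicate 3 (adjusted p of 5.33e-06 to 9.97e-05). Gzmb, a lymphocyte marker, had 22 counts in the controls and 0 with dexamethasone, and it was called without that filter (adjusted p = 0.00149). Ngp, S100a8 and Gzmb were named after their values were seen. Alas2, the erythroid enzyme of haem synthesis, stood at 0.347 ± 0.095 and 0.144 ± 0.027 CPM (SD, n = 3). It fell with an adjusted p of 0.0337 (edgeR's quasi-likelihood test, Benjamini-Hochberg). That call was lost without control replicate 2 (adjusted p = 0.167) or dexamethasone replicates 1 (0.111), 2 (0.0739) or 3 (0.0535), without the low-count filter (0.0949), with DESeq2 (0.0784) and against a fold of 1.5 (0.186).

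Counts of called members were smaller against a fold of 1.5 in most lists. Mitochondrial genes then had 0 rises and 0 falls in place of 3 and 4, and stromal markers 2 and 5 in place of 6 and 11. Cholesterol genes had 1 rise and 2 falls in place of 3 and 13, and interferon genes 5 and 2 in place of 15 and 5. Glycolysis and hypoxia genes had 4 and 2 in place of 6 and 10, which turned their balance, and p53 targets 6 and 4 in place of 8 and 8. Contractile genes had 2 and 8 in place of 6 and 11, matrix genes 5 and 11 in place of 9 and 14, and NRF2 targets 3 and 4 in place of 5 and 7. Autophagy genes had 0 rises and 2 falls in place of 3 and 6, and stress response genes 1 and 9 in place of 6 and 12. Inflammatory genes still had 24 falls, G2/M and S phase genes 25 rises each, and complement genes 12 rises.

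Camera called 12 of the 22 lists, 5 upward and 7 downward. With an estimated correlation 7 were called: glucocorticoid receptor targets, G2/M, S phase and complement upward, and inflammatory, stromal and stress response genes downward. In data simulated at these library totals and spread, 26 of 48 genes changed 1.2-fold and 47 of 50 changed 2-fold were recovered. Counts were drawn there without the steps of 2 seen at low values, so the depth in read pairs was not matched. Far fewer genes were changed there than were called here, which makes the adjusted threshold stricter. These shares therefore do not measure the recovery in this comparison. A gene that did not pass may still differ by a small amount.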

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

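Counts tested with the coefficient of variation set to 0.2, against a fold of 1.5 and on halved counts were chosen after the data were seen. The first gave 3693 changed genes, 1993 higher and 1700 lower, and the second 2827, 1549 and 1278, against 9027, 4559 and 4468. The fold of 1.5 asks more of every gene by construction. The set coefficient of variation, used with a likelihood ratio test, can ask less of genes whose estimated spread is larger. Of its 3693 calls, 3681 were shared with the main fit. Ifit1 and Ifit3, named after their values were seen, passed there (adjusted p = 6.45e-09 and 1.24e-07), against 0.219 and 0.11 in the main fit. Halved counts gave 8870. Under the planned settings the number of changed genes ranged from 8497, with a filter at 1 CPM, to 9187, with no filter, and from 8570 to 8757 with a replicate left out. No gene called both ways had the opposite sign under any setting. Library size alone put 55.3% of calls higher against 50.5%, and moved the median fold change by 0.038 on the log2 scale. The counts gave no sign that replicate numbers pair the libraries: correlations of deviations were 0.0019, 0.042 and 0.062 for equal numbers, and not every library correlated best with its own number. Such values cannot exclude a pairing of cultures, which the labels leave open. With the replicate number as a block, 8991 genes were called, 8937 of them shared, and the chondrocyte and NRF2 lists lost their calls (adjusted p = 0.167 and 0.0925). Camera with an estimated correlation called 7 lists and fry 21, against 12. Of 92 named genes with a test, 90 were called, and no call turned its direction. Lists were not tested with DESeq2, the set coefficient of variation or the fold of 1.5. Over the other settings but fry, adjusted p ranged from 0.0029 to 0.206 for the osteoblast list, 9.2e-05 to 0.592 for the chondrocyte, 1.8e-06 to 0.0658 for the matrix, 0.00146 to 0.0658 for the Wnt antagonist, 0.0252 to 0.365 for the NRF2, 0.0438 to 0.36 for the contractile and 0.0216 to 0.252 for the cholesterol list. For Alas2 it ranged from 0.0271 to 0.186 over the settings that kept the gene. For Nr3c1, Ccnd1, Egfl7, Fdft1, Map1lc3b, Gabarapl2 and the 3 named mitochondrial genes, only the set coefficient of variation and the fold of 1.5 ended calls. The cause of the other lost calls was not tested.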

Other observations

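The 6 lists below, the tests of scaling and of macrophage transcripts, and the test with a set coefficient of variation were chosen after the results were seen, so these lists are no independent evidence of their direction. The genes named here were chosen after their values were seen as well. Genes that restrain BMP signalling or report TGF-beta and activin activity fell: of 16 tested, 12 fell, 3 rose and 1 did not pass, with a median log2 fold change of -1.50 (camera, adjusted p = 9.6e-27 over the 6 lists, and 0.00184 with an estimated correlation). Chrdl2, a secreted BMP antagonist, fell by 5.76 on the log2 scale. Inhba, an activin subunit, and Pmepa1, a TGF-beta target, fell as well (log2 -4.54 and -5.05), while Fst, the activin antagonist follistatin, rose by 1.93 on the log2 scale. Of 13 tested prostaglandin genes, 10 fell, 2 rose and 1 did not pass, with a median of -2.16 (adjusted p = 8.8e-21, and 0.0045 with an estimated correlation). Ptgs2 and Ptgs1, the cyclooxygenases, fell (log2 -7.04 and -3.94), and Anxa1, which encodes annexin A1, rose (1.17). Of 23 tested growth factor genes, 14 fell and 9 rose (median -1.20, adjusted p = 7.4e-05, and 0.0138 with an estimated correlation). Igf1 and Hgf fell (log2 -5.22 and -3.46), whereas Gas6 and Pdgfd rose (3.91 for both). Igf2 rose from 6 to 88 counts, a ratio of 14.7 (95% interval 4.70 to 73.8).

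Caveolar genes rose, 7 of 8 tested, with a median log2 fold change of 1.59 (camera, adjusted p = 3.9e-11, and 0.0138 with an estimated correlation). Cav1 and Cavin2 rose (log2 2.62 and 4.44), and Cavin4, known from muscle, fell (-2.29). Of 15 tested genes of xenobiotic oxidation and conjugation, 11 rose, 1 fell and 3 did not pass, and 12 rose adjusted over the list alone (median 1.93, also with Aox3 at its bound, adjusted p = 5.8e-15, and 0.0045 with an estimated correlation). Aox1, Sult1a1 and Ugt1a6 rose (log2 4.22, 5.10 and 3.24), and Cyp1b1 fell (-1.54). Of 15 tested clock genes, 12 fell, 2 rose and 1 did not pass (median -0.70, adjusted p = 0.00263, and 0.0325 with an estimated correlation). Against a fold of 1.5, 5 of these falls and 1 rise passed, and with the coefficient of variation set to 0.2, 8 and 1. The other rise, Arntl (log2 0.13), was also lost with DESeq2 (adjusted p = 0.0565) and without control replicate 1 (0.0521) or 2 (0.067) or dexamethasone replicate 2 (0.277). The fall of Clock (log2 -0.11) was lost with library size alone (0.14) and without control replicate 1 (0.0643) or 2 (0.0722) or dexamethasone replicate 1 (0.257). Ciart and Bhlhe40 fell (log2 -2.88 and -2.52) while Per1 rose (1.63). Samples were labelled with a day and no hour, so a shift of the clock was not tested.

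The number of changed genes was the 1st pattern weighed. A bias by gene length stays open: of 3528 genes each, 51.2% of those with the shortest exons were called and 73.2% of those with the longest, a ratio of 0.699 that lay between the bounds set before it was computed. It replaced a correlation of length with the signed fold change, which could not show a bias acting in both directions. The shortest genes also had a lower median level, at 5.06 against 35.4 CPM. The count rests in large part on the very low spread between the libraries, as 3693 of 14111 genes passed with a coefficient of variation of 0.2 against 9027 with the estimated 3.66%. Since most calls were under 2-fold, so large a set value had to lower the count. The test therefore cannot tell whether the estimated spread is too low. Whether the replicates were technical stays open. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real split, the real one itself with 9027, the highest other split gave 0, and 10 splits are too few for a share under 0.05.

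The rise of cell cycle genes was the 2nd pattern. Over the 4 scalings compared, the median log2 fold change of the G2/M genes ranged from 1.45 to 1.49. Those scalings moved the median fold change of all genes by at most 0.038 on the log2 scale. The test could therefore hardly have come out otherwise, and it leaves open an error of scale that all 4 share. Dilution of the controls by non-dividing macrophages does not account for the rise, since the tested macrophage markers had a median of 1.0 CPM in the controls. An effect of dexamethasone, the difference the design names, stays open and was not tested apart from the comparison itself. Cell density and medium stay open as well and were not tested.

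The fall of inflammatory genes was the 3rd pattern. Macrophages in the control cultures are a candidate source of such transcripts, and their tested markers had a median log2 fold change of -1.23, which lay between the bounds first set for it and decided nothing. That test was replaced, after its value was seen, by a test on abundance, which argues against them: Lyz2, Cd74, Tyrobp, Fcer1g, Ctss and Laptm5 together made 2.48 CPM in the controls, 0.0201% of the 12300 CPM of the inflammatory list, with Tyrobp and Laptm5 at 0 counts. An effect of dexamethasone on the stromal cells, the difference the design names, stays open and was not tested apart from the comparison itself. Why the controls held 3899 CPM of Cxcl3 stays open.

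Genes changed at least 4-fold lay next to each other more often than by chance. Among neighbouring tested genes with no shared exon bases, 105 pairs changed in the same direction, 45 up and 60 down, against a mean of 24.5 and a maximum of 47 in 10000 permutations of positions within chromosomes (permutation p = 1e-04, the smallest they can give). Examples, chosen after their values were seen, are Pla2g4a and Ptgs2 (log2 -3.69 and -7.04), Il1a and Il1b, and Ccl2 and Ccl7. Transcripts running on into the next gene could give such pairs, but not those that point away from each other, of which there were 21 against a permuted mean of 6.37 and a maximum of 16 (permutation p = 1e-04, the smallest possible). That test argues against run-on transcription for these 21 pairs only, and it was set after the list of pairs had been seen. Some of the 105 pairs include genes named after contigs, at times with nearly the same fold. Tsc22d3 and AABR07040840.1 (log2 2.88 and 2.86) and AABR07044635.1 and AABR07044635.2 (-3.95 and -4.06) are examples, while Vegfa and AABR07066820.1 differed (-3.23 and -7.56). Whether the members of such pairs are separate genes was not tested. For the pairs that do not point away, run-on transcripts, related genes in clusters and shared regulation of a region may each contribute.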
